A study of Mus musculus with 3 samples.

How the data were processed

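Only processed files were used: UMI count matrices as deposited by the authors, a table of cells with the authors' state labels, and TCR contig tables. Per the submitters' processing notes, Cell Ranger made the counts against mm10, with no version given in the sources used here. Per the labels' protocols, muscle was injured with 0.03 mL of cardiotoxin at 0.03 mg/mL, tissue was digested with collagenase II and dispase, and cells were sorted by Foxp3-Gfp. Vancomycin was given at 0.5 mg/mL and the other 3 antibiotics at 1 mg/mL. The metadata name an SPF arm and no vehicle arm, and these were taken to be the same. Gene symbols were matched to GENCODE M21 (GRCm38), and 53292 of 55487 matched. Every sample was sorted as Tregs, so 2 planned comparisons of Tregs with other CD4 T cells were not run. No doublet caller was run, and 0.59% to 8.54% of the cells of a mouse and tissue had at least 2 β chains.

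For muscle and colon, UMIs were summed per mouse and tissue (at least 20 cells) or per mouse and class (at least 10 cells for shared cells). edgeR 4.0.16 quasi-likelihood fits with TMM scaling, its low-count filter and the mouse as a block gave log2 changes, SE and Benjamini-Hochberg adjusted p, with 0.05 as threshold. Pairing was kept because classes of a mouse come from the same animal. DESeq2 1.42.0 and limma 3.58.1 (camera with preset correlation 0.01, camera with estimated correlation, fry) were the other tools, in R 4.3.3. Of 21 lists written before any value was read, those with enough measured members were tested, among them the Helios and ST2 programme, Treg core, resting lymphoid, gut homing, inflamed tissue homing, Th17, Th1, cycling, interferon response, immediate early and heat shock, TCR signalling, repair and effector molecules, glycolysis, cholesterol synthesis, and 3 marker lists of other cell types. The myeloid, CD8 with γδ and NK, and erythroid lists had too few measured members to test. List p values were adjusted over the 18 lists tested for muscle against colon and the 14 for shared cells. Some planned results, 1 of these lists among them, are not reported here.

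Genes were named by a fixed rule: the 10 largest log2 changes each way among genes that passed with at least 50 CPM in 1 group and the same direction in every mouse, up to 4 per list by adjusted p, and 10 fixed genes. Without replicates the rule took the 10 largest log2 ratios each way among genes with at least 50 UMIs over both conditions, up to 4 per list by size, and the same fixed genes. Exceptions are stated where they occur. The 8 genes of the tissue figure were picked by hand from these. Simulated changes of 1.5, 2, 4 and 8-fold in 200 genes were found in 48%, 88%, 90% and 88% of cases for muscle against colon, and in 4%, 16%, 72% and 82% for shared cells.

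Clonotypes were pairs of α and β CDR3 nucleotide sequences with V and J names. Both chains were found in 77.4% ± 7.7 of colon and 76.4% ± 8.4 of muscle cells. For expansion, equal numbers of cells per tissue of a mouse were drawn. Shares were tested by exact two-sided sign-flip permutation over mice, where 6 mice give at least p = 0.0312, 5 give 0.0625 and 3 give 0.25.

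The antibiotic and Maf set has no mouse column, so it has 1 value per condition. Log2 ratios used CPM + 10 and genes with at least 50 UMIs, intervals came from exact Poisson and binomial limits and 500 Poisson resamples, and list medians were placed among 10000 random lists matched on expression in 50 bins. The first library was clustered with scanpy 1.11.5 and leidenalg 0.10.2 (10000 counts per cell, 2000 variable genes, 20 components, 15 neighbours, resolution 0.6), and clusters were named only from markers fixed beforehand. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used.

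The state tests in shared cells, runs in 1 batch, the run without rRNA genes, clonotypes by CDR3 alone, sharing within or between batches and the comparison of the reference arms were chosen after the data were seen.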

Results

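Regulatory T cells (Tregs) are CD4 T cells that express the transcription factor Foxp3 and restrain immune responses. They were sorted by flow cytometry 3 days after hindlimb muscle was injured with cardiotoxin, a venom toxin that destroys muscle fibres, and read by droplet RNA sequencing with unique molecular identifiers (UMIs). The first set was 1 library of muscle Tregs with 2734231 UMIs in all and a median of 1252.5 UMIs per cell. The second set held muscle Tregs of 4 conditions. There were 380 cells of vehicle mice (1576489 UMIs, median 4081.5 per cell) and 389 cells of mice given VMNA, a mixture of vancomycin, metronidazole, neomycin and ampicillin, in their water for 3 weeks (1648002 UMIs, median 4152). There were 228 cells of Maf_wt mice (968797 UMIs, median 4166.5) and 324 cells labelled Maf_ko, by the labels from mice with Maf deleted in Foxp3-expressing cells (1525388 UMIs, median 4670.5). The last set held 3918 colon Tregs and 1529 muscle Tregs of 6 mice in 2 batches, with T cell receptor (TCR) sequences. Summed per mouse and tissue, these libraries held 314990 to 3571369 UMIs. The median UMIs per cell in batch 1 were 3257.5 in colon and 3404.8 in muscle, and in batch 2 they were 1502 and 1701.5, each a mean over 3 mice.

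The study asks whether Tregs of the gut travel to injured muscle and act there. The comparison of muscle with colon Tregs in the same 6 mice shows how far the cells of injured muscle and of colon differ. Colon Tregs expressed far more Il10, the anti-inflammatory cytokine, and Lag3, an inhibitory receptor, than muscle Tregs. Il10 stood at 789.7 ± 36.7 CPM (UMIs per 1e6 UMIs of the sample; SD, n = 6) in colon and 52.4 ± 23.5 in muscle, a log2 change of -3.90 (SE 0.147, adjusted p = 2.20e-10). Lag3 stood at 520.5 ± 110.3 and 24.0 ± 10.2 CPM (log2 -4.46, SE 0.111, adjusted p = 1.77e-26). Muscle Tregs expressed more Ccr3, the eotaxin receptor (log2 3.07), and Cd7, a T cell surface protein (log2 3.57). Of 6692 genes tested with edgeR and the mouse as a block, 2508 passed an adjusted p of 0.05, 1282 higher in muscle and 1226 lower.

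Maf, a transcription factor that drives Il10, stood at 633.4 ± 86.8 CPM in colon and was lower in muscle (log2 -1.02, SE 0.074, adjusted p = 1.86e-13), and Ahr, the aryl hydrocarbon receptor that senses gut ligands, fell by 1.64 on the log2 scale. The chemokine Ccl4 (log2 -4.62) and Csf1, the macrophage growth factor (log2 -2.89), were lower as well. Of 11 interferon-response genes, a list fixed before the data were examined, 10 rose and 1 fell (camera adjusted p = 9.52e-21, and adjusted p = 0.0453 with an estimated correlation). Ifit1, an interferon-induced RNA-binding protein, rose by log2 2.62, Rtp4 by 2.32, Ifi27l2a by 1.55 and Isg20 by 1.32.

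Of 16 immediate early and heat shock genes, which also respond to tissue digestion, 3 rose and 9 fell (camera adjusted p = 3.63e-05, but adjusted p = 0.3996 with an estimated correlation). The chaperones Hspa1b (log2 -4.60) and Hspa1a (log2 -4.40) and the phosphatase Dusp1 (log2 -1.44) were lower in muscle. Of 15 Treg core genes 4 rose and 8 fell (camera adjusted p = 0.0230, but adjusted p = 0.3996 with an estimated correlation). Foxp3 rose by log2 0.46 and Ikzf2, the transcription factor Helios of thymus-derived Tregs, by 0.73. Tigit, an inhibitory receptor, fell by 1.18 and Nt5e, the ectonucleotidase CD73, by 1.16 on the log2 scale. The Ikzf2 call (adjusted p = 0.0230) was lost without mouse 1 of batch 1 (adjusted p = 0.0611), mouse 1 of batch 2 (0.0629) or mouse 2 of batch 2 (0.0503). The Foxp3 call was lost without the mouse block (adjusted p = 0.258).

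The other lists did not pass camera, which ranks a list against all other genes. By fry, which asks only whether a list moved, 12 of the 17 lists passed, among them Th1 (down, adjusted p = 2.66e-04), gut homing (down, 0.00275), cholesterol synthesis (down, 0.0106), Th17 (down, 0.0120), resting lymphoid (up, 0.0151), repair and effector molecules (down, 0.0156), inflamed tissue homing (up, 0.0173) and cycling (up, 0.0379). In the Helios and ST2 list 3 of 10 genes rose and 2 fell (4 and 2 with p adjusted over the list alone; camera adjusted p = 0.612). Il1rl1, the interleukin-33 receptor ST2, rose by log2 0.90 and Nrp1, a marker of thymic Tregs, by 2.29, while Ccr8, a skin and tissue homing receptor, fell by 1.19. Areg, the repair factor amphiregulin (log2 -0.49, adjusted p = 0.108), and Gata3 (log2 -0.11, adjusted p = 0.435) did not pass. Gut homing genes went both ways, 3 up and 4 down of 7 (camera adjusted p = 0.135). Ccr9 (log2 -4.53) and Gpr15 (log2 -2.62), receptors that direct T cells to small intestine and colon, were lower in muscle, as was the integrin Itga4 (log2 -2.20), while Itgae, the CD103 integrin that binds epithelium, was higher (log2 1.26). Of 11 inflamed tissue homing genes 5 rose and 3 fell (adjusted p = 0.102), among them Itgb1 (log2 1.60) and Selplg (log2 0.71). Of 8 resting lymphoid genes 4 rose and 2 fell (3 fell with p adjusted over the list alone; adjusted p = 0.244), with S1pr1, the exit receptor of lymph nodes, up by log2 1.35 and Tcf7 at -0.99. Of 7 cycling genes 3 rose and 2 fell (3 fell with p adjusted over the list alone; adjusted p = 0.612). Mki67, a proliferation marker, stood at 12.96 CPM in colon and rose by log2 1.42, and Top2a rose by 1.34.

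Of 6 Th17 genes 2 fell (adjusted p = 0.135), Ccl20 (log2 -2.90) and Rora (log2 -0.53). Il17a, the Th17 cytokine, stood at 40.8 CPM in colon and 10.1 in muscle and did not pass (log2 -1.94, adjusted p = 0.0646). Of 7 Th1 genes 1 rose and 3 fell (adjusted p = 0.148), including Nkg7, a cytotoxic granule protein (log2 -1.74). Of 12 TCR signalling genes 3 rose and 4 fell (adjusted p = 0.904), with Nr4a1 at log2 1.24 and Irf4 at -0.68. Of 12 repair and effector genes 4 rose and 4 fell (5 fell with p adjusted over the list alone; adjusted p = 0.148), of 11 glycolysis genes 4 rose and 2 fell (adjusted p = 0.968), and of 9 cholesterol synthesis genes 0 rose and 5 fell (adjusted p = 0.135). For the Helios and ST2 and the cycling lists the median was below 0 while the mean and the test pointed up, and the glycolysis, TCR signalling, B and plasma cell and colon epithelium lists also differed in sign between these measures. Markers of other cell types did not pass camera, while fry called those of muscle and stroma, lower in muscle (adjusted p = 0.00800). By camera, for B and plasma cells 2 of 5 rose and 2 fell (adjusted p = 0.968), for muscle and stroma 1 of 3 fell (adjusted p = 0.479), and for colon epithelium 1 of 7 rose and 1 fell (adjusted p = 0.904). Epcam stood at 92.8 CPM in colon (log2 -0.54). The share of UMIs on the ribosomal RNA gene CT010467.1 was 5.40% ± 1.51 in colon and 5.91% ± 1.48 in muscle (SD, n = 6).

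DESeq2, given 20845 genes against 6692 for edgeR, called 1508 at the same threshold, 1330 of them shared with edgeR, and batch 1 and batch 2 alone gave 2074 and 1632. Tissue, digestion and injury go together in this design, since cardiotoxin was given to the muscle. Their parts in these differences cannot be told apart.

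**Figure D1:**
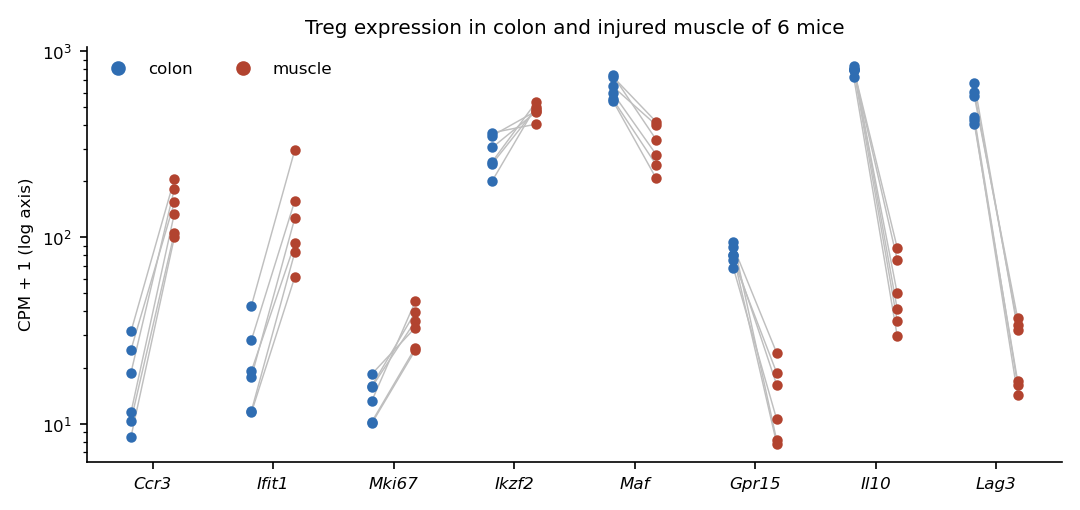
CPM plus 1 (log axis) of 8 genes picked from the named genes, in colon (blue) and muscle (red) Tregs, with a point per mouse and lines joining the tissues of a mouse (n = 6). Il10 and Lag3 were lower in muscle in 6 of 6 mice, and Ccr3 and Ifit1 were higher in 6 of 6.

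The authors' annotation gives each cell a state. In muscle the EarlyAct state held 33.8% ± 5.3 of Tregs (SD, n = 6), the reparative state 29.4% ± 4.1 and the interferon-responding ISG state 11.5% ± 5.0.

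TCR sequences tie cells to clones, since cells with the same α and β chains descend from 1 ancestor in nearly all cases. Of muscle Tregs with both chains, 5.98% ± 3.34 (SD, n = 6) had a clonotype that was also found in the colon of the same mouse, against 0.0884% ± 0.156 for the colons of other mice. The own-colon share was higher in 6 of 6 mice (exact two-sided sign-flip permutation p = 0.0312, the smallest 6 mice can give), by 7.08 points in batch 1 and 4.70 in batch 2. With clonotypes by the β chain alone the shares were 9.55% and 0.863%, and without mouse 2 of batch 1 the share for other mice was 0.0292%. Over all mice this was 71 of 1124 cells and 40 clonotypes. By state, with all mice together and exact binomial intervals for counting error only, 6.21% (20 of 322, 3.83 to 9.43%) of reparative, 5.34% (7 of 131, 2.17 to 10.7%) of ISG and 3.76% (14 of 372, 2.07 to 6.23%) of EarlyAct cells were shared. These 3 states do not cover all muscle cells. In colon 1.82% (56 of 3076, 1.38 to 2.36%) of all cells and 0.749% (7 of 934, 0.302 to 1.54%) of Helios-state cells were shared with muscle. Cells of 1 clone are shared together, so these intervals treat linked cells as separate and are too narrow.

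Per mouse, the EarlyAct state held 33.0% ± 33.7 of colon-shared and 35.0% ± 4.9 of other muscle cells (exact permutation p = 0.906), and was lower in the shared cells in 5 of 6 mice. Mouse 1 of batch 2 had 1 shared cell, in this state. Without that mouse the shares were 19.6% and 34.2%, lower in 5 of 5 mice (exact permutation p = 0.0625, the smallest 5 mice can give). With clonotypes by the β chain alone the difference was -16.4 points (exact permutation p = 0.0625). The reparative state held 23.3% ± 15.1 and 28.4% ± 3.8 (exact permutation p = 0.625), and ISG 12.1% ± 12.7 and 11.7% ± 4.9 (exact permutation p = 0.938). None passed (adjusted p = 0.938 for each over a family of 4 tests made after the data were seen). The EarlyAct difference was -15.3 points in batch 1 and 11.2 in batch 2, where 1 of 3 mice, that with 1 shared cell, was higher. The reparative difference was 0.641 and -10.8 points, 0.783 without that mouse and -11.8 with 1 value per clonotype, and the ISG difference 3.70 and -2.83, and 1.32 without that mouse.

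**Figure D2:**
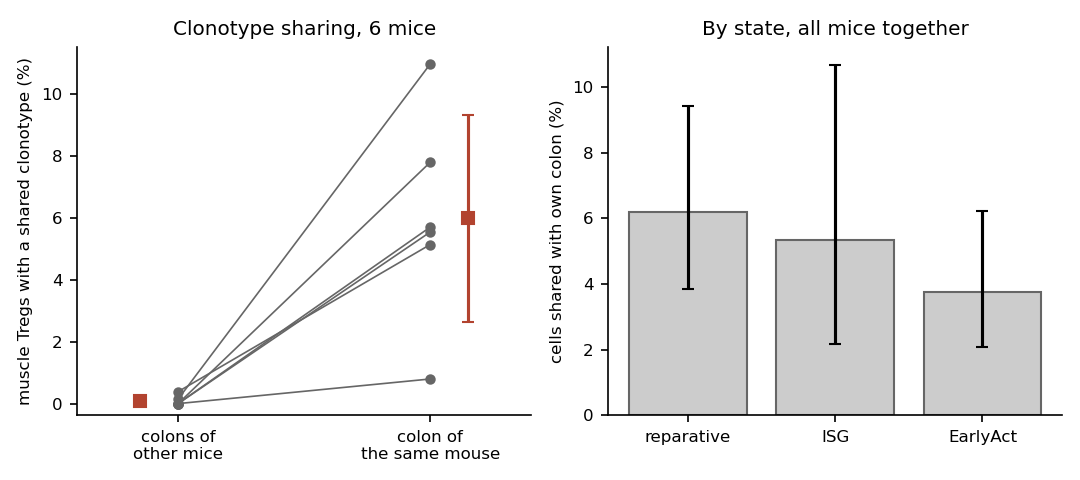
Left, percent of muscle Tregs per mouse (points, n = 6; squares, mean ± SD) whose clonotype was found in the colons of other mice or of the same mouse. Right, percent of muscle cells of 3 states shared with the own colon, all mice together, with exact 95% binomial intervals that treat cells of a clone as separate.

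Expression of colon-shared and other muscle Tregs could be compared in 3 mice with at least 10 shared cells. Lars2, a mitochondrial leucyl-tRNA synthetase, was lower in the shared cells, from 2440 ± 668 CPM (log2 -0.69, SE 0.159, adjusted p = 0.0206, lower in 3 of 3 mice). Trbv19 and Trbv20, the TCR segments that also define the clones, were the other 2 of the 3 genes that passed edgeR's test among 3250, and 132 had an unadjusted p under 0.05. These segments fall outside the rule for named genes and are named because the count is small. Maf (log2 -0.12), Ikzf2 (log2 -0.52), Cxcr6, a tissue residence receptor (log2 0.81), Tmem176b (log2 1.20), Il10 (log2 -0.11) and Areg (log2 0.60) did not pass. The interferon list had camera adjusted p = 3.65e-04 with 0 of 11 genes past the threshold (3 lower with p adjusted over the list alone), but adjusted p = 0.898 with an estimated correlation. Lars2 in the other cells stood at 1681, 2704 and 2935 CPM in mouse 3 of batch 1 and mice 2 and 3 of batch 2. The ribosomal RNA gene CT010467.1 held 4.40%, 6.34% and 7.59% of their muscle UMIs, the same order. Shared cells were not run without rRNA genes. The Lars2 call was lost with DESeq2, which called 0 genes (55 with an unadjusted p under 0.05), without the mouse block (0 genes), and without mouse 3 of batch 1, mouse 2 of batch 2 or mouse 3 of batch 2. The count was 1 without mouse 3 of batch 1, 17 without mouse 2 of batch 2 and 12 without mouse 3 of batch 2, so it rests on single mice. Swapping the labels within mice gave at least as many genes (median 9, highest 11), so the count of 3 was not above that of swapped labels.

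Clones were larger in muscle when equal cell numbers were compared. In a clone of at least 2 cells were 34.6% ± 7.9 of muscle and 18.7% ± 5.9 of colon Tregs (higher in muscle in 6 of 6 mice, exact permutation p = 0.0312, the smallest possible), 16.8 points apart in batch 1 and 15.1 in batch 2. With all cells of each tissue, where colon had more cells in 5 of 6 mice, the difference was 0.497 points (exact permutation p = 0.906), and for clones of at least 3 cells it was 13.4 points (exact permutation p = 0.0625). Muscle held 837 clonotypes, 137 of at least 2 cells and the largest of 16, and colon held 2382, 403 of at least 2 cells and the largest of 25.

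The antibiotic comparison asks what muscle Tregs look like when the gut microbiota is depleted. It has 1 set of cells per condition with no map to mice, so values are given without tests, and intervals cover counting error only. The EarlyAct state held 17.6% (13.9 to 21.8%) of vehicle and 36.8% (32.0 to 41.8%) of VMNA cells, the reparative state 26.8% and 29.8%, and the ISG state 11.1% and 13.4%. These 3 states do not cover all cells, and a share also moves when that of the other cells does. Between vehicle and Maf_wt, both reference arms, EarlyAct also differed, at 17.6% and 28.1%, so it can differ apart from the antibiotics. These arms are controls of different comparisons, so their difference does not measure the spread between repeats of 1 condition. The Helios and ST2 list was higher in VMNA, with 6 of its 9 measured genes higher and a median log2 of 0.48 (0.28 to 0.54), at percentile 100 of 10000 random lists matched on expression. Within reparative, EarlyAct and ISG cells the median was 0.305, -0.12 and 0.69, without intervals or a test between states. Genes of a list can move together and the random lists do not keep this, so here and below a percentile is no test.

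Cxcr6 stood at 120 CPM in vehicle and 25.5 in VMNA cells (log2 -1.87), Maf at 724 and 549 (log2 -0.40), Il10 at 101 and 71.6 (log2 -0.44), Lag3 at log2 -0.57, Havcr2 at -0.57, Tmem176a at -0.63 and Itgae at -0.50. These values are over all cells, so they also move with the shares of the states. Il17a was found in 24 and 8 UMIs, but 16 of the 24 lay in 2 vehicle cells with at least 5 UMIs of Trdc, a gamma delta TCR gene, and without such cells it stood at 5.10 CPM in vehicle and 4.89 in VMNA. Higher in VMNA were Tnfrsf9, the costimulatory receptor 4-1BB (811 against 348 CPM, log2 1.20), Il1rl1 (228 against 103, log2 1.08), Ikzf2 (1319 against 940, log2 0.48), Gata3 (log2 0.55), Batf, a transcription factor of tissue Tregs (log2 0.58), Tnfrsf18 (log2 0.52) and Tnfrsf4 (log2 0.43). Within reparative, EarlyAct and ISG cells Ikzf2 stood at log2 0.07, -0.12 and 0.70, Il1rl1 at 0.61, 0.48 and 1.32, and Tnfrsf9 at 1.25, 1.80 and 0.87. The Treg core list had a median of 0.33 (percentile 100), TCR signalling of 0.27, Th1 of 0.31 and Th17 of -0.41. Within reparative, EarlyAct and ISG cells these were 0.09, 0.07 and 0.515 for Treg core, 0.20, -0.08 and 0.54 for TCR signalling, -0.31, 0.195 and 0.54 for Th1, and -0.19, -0.56 and 0.20 for Th17. Foxp3 (log2 0.10), Areg (log2 0.01) and Mki67 (log2 0.17) stood close together. The largest differences by the fixed rule also took in Itga4 (log2 1.49), Ifitm2 (log2 1.48), Faim (log2 1.00), Dusp10 (log2 0.97) and Dgat1 (log2 0.90) as higher, and Mmp25 (log2 -1.23), Sdf2l1 (log2 -1.16), Prg4 (log2 -1.16) and Socs2 (log2 -1.12) as lower. Between vehicle and Maf_wt, the reference arms, Itga4 differed by log2 -1.72 and Dusp10 by -1.46, Il10 by 1.33, Lag3 by 1.20, Maf by 1.02, Tnfrsf4 by 0.88, Havcr2 by 0.77 and Itgae by 0.63, each more than VMNA from vehicle. Tnfrsf9 differed by 1.16, Il1rl1 by -0.82, Gata3 by -0.51, Cxcr6 by -0.44 and Ikzf2 by -0.06. The list medians were -0.22 for Helios and ST2, 0.44 for Treg core, -0.93 for Th1, -0.07 for TCR signalling and -0.125 for Th17. Log2 ratios of vehicle over Maf_wt had an SD of 0.308 over 5121 genes, against 0.237 for VMNA over vehicle and 0.254 for Maf_ko over Maf_wt. Maf_wt had the fewest UMIs, so ratios to it hold more counting error.

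**Figure D3:**
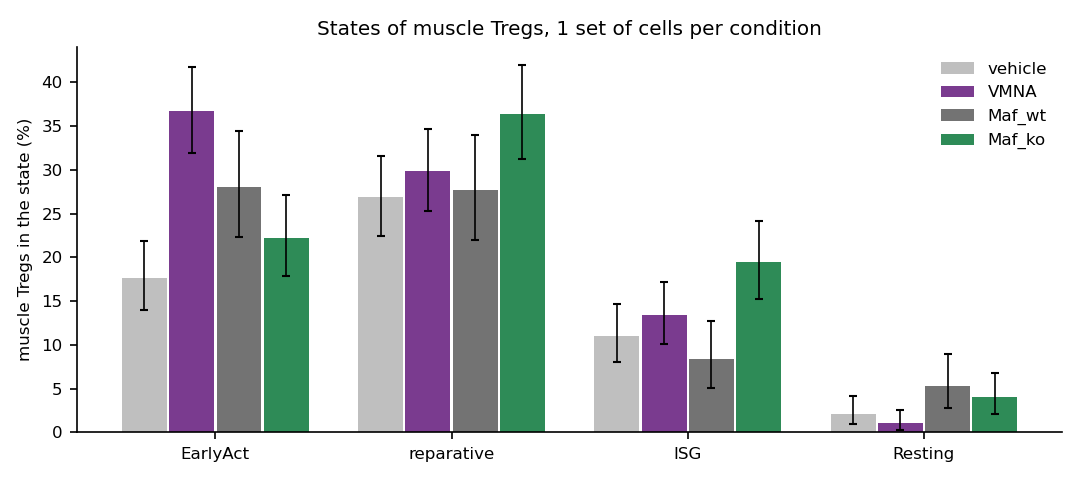
Percent of muscle Tregs in 4 of the authors' states for vehicle, VMNA, Maf_wt and Maf_ko cells (bars, 1 set of cells per condition), with exact 95% binomial intervals for counting error only. The EarlyAct state stood at 17.6% in vehicle and 36.8% in VMNA cells, and the ISG state at 8.33% in Maf_wt and 19.4% in Maf_ko cells.

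Deleting Maf asks whether this factor shapes the muscle Tregs. Maf (chromosome 8 at 115682942 to 115707794, minus strand) stood at 326 CPM in the cells labelled Maf_ko and 351 in Maf_wt (log2 -0.10). Within ISG cells, only 63 and 19 of them, it stood at 434 and 161 CPM. Whether the tags lie inside the deleted part was not looked up, so these counts do not show a loss of Maf and the label is taken as given. The ISG state held 8.33% (5.09 to 12.7%) of Maf_wt and 19.4% (15.3 to 24.2%) of the cells labelled Maf_ko. The reparative state held 27.6% and 36.4%, and EarlyAct 28.1% and 22.2%. All 12 measured interferon-response genes were higher in the cells labelled Maf_ko (median log2 0.66, percentile 100), among them Ifit3 (log2 0.87), Bst2 (log2 0.86), Zbp1 (log2 0.80) and Irf7 (log2 0.72). Within reparative, EarlyAct and ISG cells the median was 0.08, 0.14 and 0.09. The ISG state is itself the interferon-responding state, so its share and this list are not separate results. All 12 genes of the list measured in the reference arms were also higher in vehicle than in Maf_wt cells (median log2 0.40), Ifit3 by 1.26, Zbp1 by 0.71, Bst2 by 0.48 and Irf7 by 0.46, so Maf_wt was the lower of the 2 reference arms for this list. Over all cells Cxcr6 stood at log2 -0.52 and Il10 at 0.66 (59.7 against 34.1 CPM), and the Helios and ST2 list had a median of -0.01 (percentile 38.7). Within reparative, EarlyAct and ISG cells the median of that list was 0.20, 0.03 and -0.27.

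Higher in the cells labelled Maf_ko were Penk, an enkephalin precursor (log2 1.70), Serpinb1a (log2 1.49), Pdcd1 (log2 1.27), Tnfrsf9 (log2 0.83), Ccl5 (log2 0.79) and Gzmb, a cytotoxic protease (log2 0.67), with Hyi (log2 1.53), Serpinb6b (log2 1.498) and Lgals3bp (log2 1.18). Lower were Cpm, a carboxypeptidase (log2 -1.73), Ccr7, the lymph node homing receptor (log2 -1.43), Nt5e (log2 -0.91), Jun (log2 -0.82), Itgae (log2 -0.67) and Klf2 (log2 -0.60). Areg stood at log2 -0.37 and Ikzf2 at 0.27, both over all cells, so they also move with the shares of the states. Within reparative, EarlyAct and ISG cells Penk stood at 2.96, -1.50 and 0, Ccl5 at 0.87, 0.80 and -0.85, Tnfrsf9 at 0.37, -0.075 and 0.51, Pdcd1 at 1.25, 0.26 and 1.16, and Gzmb at 0.91, 0.20 and 0.01, while Serpinb1a, Hyi, Serpinb6b and Lgals3bp were higher and the 6 lower genes lower in all 3. The resting lymphoid list had a median of -0.42 (6 of 8 lower, percentile 0), Treg core of 0.22 (percentile 100) and repair and effector molecules of 0.21 (percentile 99.9). Within reparative, EarlyAct and ISG cells these were -0.10, -0.19 and -0.65, then 0.205, 0.06 and -0.08, and 0.42, 0.01 and 0.01. Vehicle over Maf_wt cells had medians of -0.47, 0.44 and 0.09 for the 3 lists, so for resting lymphoid and Treg core the reference arms differed by more, in the same direction. Il17a was found in 0 UMIs, with an exact upper limit of 2.42 CPM, and in 11 UMIs in Maf_wt, which lay in 2 of 228 cells. Iigp1, an interferon-induced GTPase, was higher by log2 1.18, but differed by 2.05 between vehicle and Maf_wt, as did Il10 by 1.33, Tnfrsf9 by 1.16 and Penk by 0.98.

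The first library alone fell into 5 clusters, of which 1 could be named from markers fixed beforehand. An interferon-responding-like cluster held 191 cells (9.46%, 8.21 to 10.8%), led by Ifit1, Ifit3 and Isg15. Another, of 357 cells (17.7%), was led by Cxcr6, Ltb4r1 and Adam8 and had the lowest Ikzf2 (372 CPM) of the 5. A cluster of 466 cells (23.1%) was led by Cd83, Tnfrsf9 and Cd74, with Areg at 632 and Ikzf2 at 1265 CPM. The other 2, of 681 and 325 cells, were led by Fos, Klf6 and Tagap and by Ccr7, Trat1 and Dusp10. The clusters changed with the settings: resolutions of 0.3 and 1 and a stricter filter gave 2, 10 and 6, with an adjusted Rand index of 0.074, 0.444 and 0.222 to these 5. The interferon-responding-like cluster was found each time, and the stricter filter also gave 1 of 64 cells led by Cxcl14, Ccr7 and Ccl2, with the stromal gene Sparc among its top 6. Ighm and Igkc, genes of B cells, stood at 780 and 133 CPM over all cells, Dcn and Col3a1, genes of stromal cells, at 421 and 347 CPM, and Foxp3, the gene of the sort, at 17.6 CPM (48 UMIs); cells and free RNA were not told apart as their source.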

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

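Tests chosen only after the result was seen are the wrong-mouse and position tests and the sample splits for muscle against colon and for shared cells.

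Muscle Tregs shared clonotypes with the colon of their own mouse. Cells given to the wrong mouse would match the colons of other mice of the batch. Those matched in 0.1335% of comparisons (0.0275 to 0.3895%), against 6.32% for the own colon (4.97 to 7.90%), all mice together. The intervals treat cells of 1 clone as separate, so they are too narrow. These percentages are the pattern itself and no separate test. They argue against wrong mice as the source of the excess, while a few such cells stay possible. Shared muscle cells lay 1.01% of the way from other muscle to colon cells (mean of mice 2.79%, SD 12.03). Most were therefore not colon cells recorded as muscle cells, but single cells of that kind are not excluded. By mouse the position ran from -8.67% to 24.5%, the latter from the 1 shared cell of mouse 1 of batch 2. The 50 genes used were picked as lower in muscle in these same cells. Free TCR RNA of large colon clones was not the source of most shared clonotypes. Of the 40, 72.5% (56.1 to 85.4%) were in 1 colon cell, and 0 were among the 5 largest colon clones of their mouse. Of all colon clonotypes 83.1% were in 1 cell, so this cannot exclude free TCR RNA of colon cells in general. Where the 6 tagged samples of a batch were pooled, free RNA would reach muscle cells of every mouse of that batch. Matches to other mice of the batch (0.1335% of comparisons, against 6.32% for the own colon) argue against it as the main source.

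Of 32 groups of 6 mice tested for a value far from the others 0 were marked, where about 1 in 20 would be by chance. Among TCR pairs of barcodes outside the cell table, 600 in batch 1 (12.4% of 4837) and 700 in batch 2 (7.204% of 9717) matched a Treg of the batch. Only 12 and 32 matched the other batch. Cells that were left out of the cell table are not analysed here.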

How the results depend on the processing

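The runs in 1 batch were chosen only after the result was seen, as were the sample splits.

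For muscle against colon, DESeq2 gave 1508 genes, batch 2 alone 1632, the run without the mouse block 2073 and the run without the low-count filter 1144 up and 1713 down, against 2508. Of 81 named genes 71 passed, 54 of them in every setting and 0 reversed.

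For shared cells, the 3 genes became 0 with DESeq2, 0 without the mouse block, 0 without cycling cells (which also left 2 of the 3 mice), 1 without mouse 3 of batch 1 and 17 without mouse 2 of batch 2.

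With an estimated correlation 1 of 3 lists held for muscle against colon and 0 of 1 for shared cells.

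Clone sharing exceeded that with other mice by 7.08 points in batch 1, 4.70 in batch 2, 4.91 without mouse 3 of batch 1 and 6.91 without mouse 1 of batch 2. The expansion difference was 16.8 points in batch 1, 15.1 in batch 2, 14.4 without mouse 2 and 17.7 without mouse 1 of batch 1, 0.497 with all cells and 13.4 for at least 3 cells.

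For VMNA the Helios and ST2 list median of 0.48 was 0.49 with median-ratio scaling, 0.488 and 0.433 with pseudocounts of 1 and 50 CPM, and 0.451 without cycling cells. This list was taken to follow VMNA and Maf deletion across settings only after its values had been seen. In the first library the interferon-responding-like cluster held 6.83% at resolution 0.3.

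The runs with at least 50 cells per sum for shared cells left too few mice and were not run, nor were the 2 comparisons with other CD4 T cells and their alternatives.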

Other observations

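The receptor families below and the sample splits were chosen only after the result was seen.

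Cells of 1 clone tended to share a state. In muscle 42.6% ± 8.9 of cell pairs of a clone were in the same state against 29.8% by shuffling, and in colon 86.7% ± 2.3 against 64.1%, each in 6 of 6 mice (exact permutation p = 0.03125 for both).

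Sample labels were also swapped in every balanced way. The real labels gave the most genes of 32 splits for muscle against colon (2508, highest other 0). For shared cells all 4 splits had at least the real count of 3 genes (median of the others 9, highest 11). The real count was thus not above that of swapped labels, though 4 splits are too few for a test.

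A receptor family with TRAV4, TRAJ42, TRBV20 and TRBJ1-1 held 69 of 3076 colon cells (2.24%) in 6 mice, made of 15 nucleotide pairs, and 1 of 1124 muscle cells. A family with TRAV13, TRAJ18, TRBV15 and TRBJ2-7 held 12 muscle cells (1.07%) in 5 mice and 0 of 3076 colon cells. Both were picked from many families.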
